A study of Mus musculus with 4 samples.

How the data were processed

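Prostates from 4 groups of mice were dissociated with collagenase and TrypLE and profiled by droplet single-cell RNA sequencing with the 10x Chromium 3' kit, version 3. Each group has 1 library. Per the labels, Trp53 was deleted in a prostate-restricted way (marked PC in the genotype) in 2 of the groups and not in the other 2, each without and with ADT. The rest of the genotype, which all groups share, and some genes measured are not reported here. The labels do not spell out ADT, which is read here as androgen deprivation therapy. The groups are called Trp53-intact, Trp53-intact ADT, Trp53-deleted and Trp53-deleted ADT, and their ages were 4, 5.5, 3.5 and 5.5 months. Since each group is 1 library and both ADT libraries came from older mice, ADT, age and library cannot be told apart, nor can genotype and library.

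The deposited matrix holds UMI counts per gene and cell barcode, which the authors made with Cell Ranger against the mm10 build and did not normalise. The submitters' notes name Cell Ranger 2.1.1, whereas the matrix header gives software version 3.1.0, and this difference could not be settled. All 4 libraries are in 1 matrix of 30905 genes and 36326 barcodes with 74090388 entries. The library of each barcode was taken from the submitters' table of barcode suffixes. Which rule had already selected the barcodes is not stated. Symbols shared by several gene identifiers (127) were kept apart by identifier. Gene positions came from GENCODE M21 on GRCm38, which held 30766 of the 30905 identifiers.

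Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Doublet scores were computed per library with Scrublet as built into scanpy. Its automatic threshold marked 0, 0, 1 and 2 barcodes, so the highest-scoring barcodes were left out instead, as a share of the library that grew by 0.008 per 1000 barcodes. This took out 591, 478, 312 and 789 otherwise kept cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes gave 40 principal components, a graph of 20 neighbours and Leiden clusters at resolution 1. The 44 clusters were named from marker lists by the highest marker score (at least 1, or 3 own markers among the 10 leading genes) unless fewer than 3 markers of the class were detected, more markers of another class stood among those 10, or the cluster was shallow with no marker of its class among them. The thresholds, and a rule that leaves a cluster unnamed when genes of a type outside the lists lead it, were set after the clusters were seen. This named 17 classes and left 9 clusters unnamed. Names are written as "-like" because they rest on RNA alone. Epithelial-like cells join the luminal-like, luminal progenitor-like and basal-like clusters, and seminal vesicle-like cells were kept apart. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

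UMIs were summed per class and library and divided by the class total to give CPM, the unit of expression used throughout. Log2 ratios used a pseudocount of 5 CPM. Intervals are exact at the 95% level (Poisson for CPM, conditional binomial for ratios of CPM, Clopper-Pearson for shares of cells), and they cover counting error only. Shares of 0 in cycling cells and the count of 0 for Pbsn are given with the level that 3 counts would have, while other counts of 0 are given as no UMI. Because no group has a replicate, no test between groups and no p-value is given, and numbers of genes higher or lower go by the size of the ratio alone, without a replicate check. The comparisons were ADT against no ADT in each genotype and Trp53-deleted mice against Trp53-intact mice without and with ADT, with no covariate.

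Before the data were examined, 26 gene lists, the comparisons, the other settings to be tried and the rule for named genes were fixed. A list member counted as measured with at least 20 UMIs over both libraries. Lists are given as the median log2 ratio and the number of measured members at least 1.5-fold higher or lower by size alone. The percentile of the median among 10000 random lists matched on expression in 20 bins, a description of these libraries, was computed for each and is printed for some. Named genes in epithelial-like cells had at least 100 UMIs over both libraries and, in the library where they were higher, a CPM at least that of every other class of 50 or more cells. Mitochondrial, ribosomal protein, haemoglobin, Gm and Rik genes were left out. The 12 highest and 12 lowest by log2 ratio with a pseudocount of 10 CPM were named. In macrophage-like, neutrophil-like, T-like, fibroblast-like and endothelial-like cells, 5 each way were ranked, with a CPM at least 0.5 of that of the highest class. Trp53 was always reported, and up to 4 members with the largest ratios each way were named per list. Values are given for the luminal progenitor-like cells too, since luminal-like cells were nearly absent from the ADT libraries. Cdkn1a, Cdkn2a and Pbsn across classes were chosen after the data were seen, as were the genes named for the unnamed clusters.

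A cell counted as cycling with UMIs of at least 2 of 10 cell cycle genes after each cell was thinned to 2000 UMIs, with shallower cells left out. Neutrophils, which do not divide, give the background. Correlations of the 2 ADT ratios were computed across genes with at least 20 CPM in a library.

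The steps were tested on data simulated from the summed counts of these libraries with counting error only. Differences between mice, between libraries, in the mix of clusters or in free RNA were not simulated. The rates below therefore do not say how often such differences pass 1.5-fold. Of genes simulated at 1.5-fold, between 97.01% and 98.51% had the true direction, at 4-fold 100.0% did, and at most 0.02% of unchanged genes passed 1.5-fold. The binomial, Poisson and ratio intervals covered the true value in 95.2%, 96.0% and 96.45% of draws. A limit on the simulated list medians was replaced after the first simulated run because it ignored the shrinkage from the pseudocount; the new limit compares them with the median expected with the pseudocount.

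The alternatives tried were a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), doublets kept, Leiden resolutions of 0.5 and 2.0, clustering each library on its own, another denominator for shares, a pseudocount of 1 CPM, trimmed mean of M values (TMM) factors, thinned cells, means over cells, a member minimum of 100 UMIs, members highest in epithelial-like cells only, and basal-like cells left out. Those added after the data were seen were a mitochondrial limit of 50%, counting unnamed cluster 3 as epithelial-like, luminal progenitor-like cells only, and all alternatives for immune classes. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.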

Results

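Single-cell RNA of prostates was counted in 4 libraries, 1 each for mice with Trp53 left intact, without and with ADT, and mice with Trp53 deleted in the prostate, without and with ADT. The libraries are called Trp53-intact, Trp53-intact ADT, Trp53-deleted and Trp53-deleted ADT. The matrix held 9401, 8524, 7806 and 10595 barcodes in that order, with 90659173, 63803901, 58088678 and 148030357 UMIs. After filtering, 7503, 7273, 5382 and 8837 cells remained, with median depths of 5462, 4129, 4459.5 and 5678 UMIs per cell. Barcodes above the mitochondrial limit made up 13.9%, 8.39%, 25.7% and 9.15%. Below, 4 values in a row follow this order of libraries.

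Epithelial-like cells made up 22.03% of cells in the Trp53-intact library (95% interval 21.1 to 22.99), 7.95% in Trp53-intact ADT (7.34 to 8.59), 9.64% in Trp53-deleted mice (8.87 to 10.5) and 2.67% in Trp53-deleted ADT (2.34 to 3.03). They came from clusters 8 and 19 (luminal progenitor-like), 9 (luminal-like) and 26 (basal-like). Cluster 9, led by secretory genes such as Defb50 and Pbsn, held 884, 9, 77 and 4 cells, so the luminal-like share follows genes that themselves differ between the libraries. Luminal progenitor-like cells were 8.38%, 6.24%, 6.47% and 2.23% of cells, and basal-like cells 1.87%, 1.58%, 1.75% and 0.396%. Of epithelial-like cells, 53.5%, 1.56%, 14.8% and 1.69% were luminal-like and 8.47%, 19.9%, 18.1% and 14.83% basal-like. The lower epithelial-like share with ADT in Trp53-intact mice, a difference of -14.08 percentage points, was +1.76 points when each library was clustered on its own and -1.45 points with cluster 3 counted as epithelial-like. In Trp53-deleted mice the difference of -6.97 points was -0.58 with each library clustered on its own. The lower share in Trp53-deleted mice without ADT (-12.39 points) and with ADT (-5.28 points) kept its direction, with -6.37 and -19.7 points as the values farthest from these. Cluster 3 stayed unnamed, was shallow (median 812 UMIs in the Trp53-intact ADT library) and carried epithelial genes such as Krt18 and Cxcl5 among its leading genes. It held 4.19%, 16.8%, 0.650% and 2.41% of cells. Cluster 32, with 0, 50, 2 and 133 cells, also stayed unnamed for a low marker score (0.843), although luminal was its best class. Its leading genes included Elf5, Clu and Olfm4, and the seminal vesicle marker Pate4. Nearly all its cells came from the ADT libraries, and the epithelial-like share with cluster 32 counted was not computed. All unnamed clusters together held 6.22%, 21.7%, 1.86% and 29.9%.

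Immune-like cells were 46.9%, 46.8%, 53.6% and 51.3% of cells, while their make-up differed. Macrophage-like cells were 18.1%, 4.66%, 11.6% and 27.8%, neutrophil-like cells 9.996%, 16.5%, 14.5% and 5.40%, and B-like cells 2.81%, 9.51%, 8.53% and 2.195%. T-like cells made up 5.09%, 9.94%, 9.09% and 7.41%, and natural killer (NK)-like cells 1.93%, 2.38%, 2.90% and 3.96%. Monocyte-like cells were 2.17%, 0.825%, 3.75% and 0.249%, and dendritic-like cells 4.36%, 1.98%, 2.06% and 3.63%. Fibroblast-like cells were 14.7%, 16.1%, 27.9% and 8.85%, and endothelial-like cells 2.88%, 2.79%, 2.77% and 5.32%. Most macrophage-like cells of the Trp53-deleted ADT library (2073 cells) came from cluster 2. Its 10 leading genes held 3 macrophage and 3 monocyte markers, and 50.14% of its cells were named monocyte-like at resolution 2.0. With doublets kept this cluster lost its name, and the macrophage-like share was then lower with ADT in Trp53-deleted mice by -6.89 points instead of higher by 16.22.

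**Figure D1:**
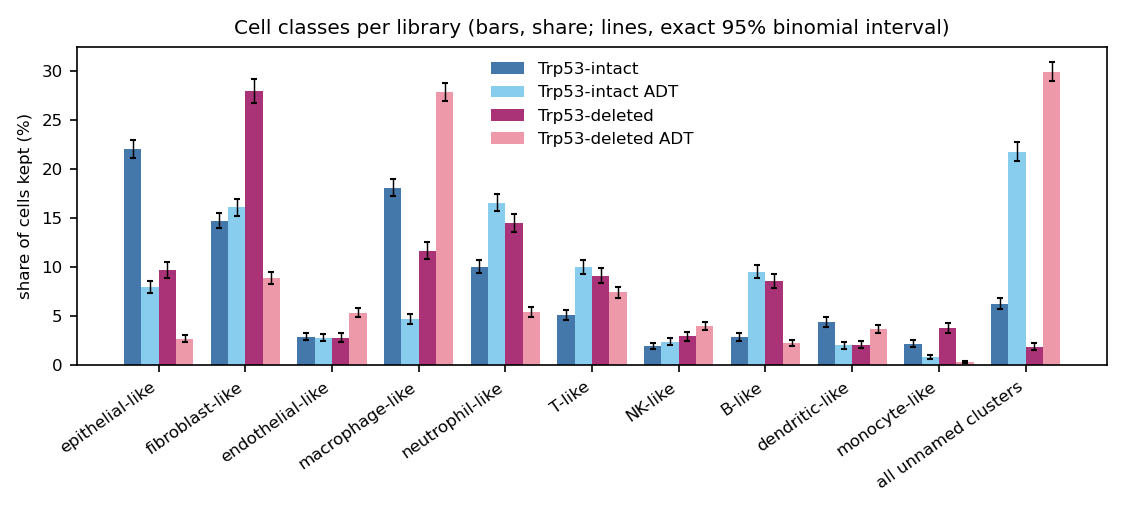
Share of the cells kept (%, vertical axis) in 10 cell classes and in all unnamed clusters, per library (colours), with exact 95% binomial intervals as lines. Epithelial-like cells stand highest in the Trp53-intact library (22.03%), macrophage-like cells in the Trp53-deleted ADT library (27.8%).

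Trp53, which encodes the tumour suppressor p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873 on the plus strand, GRCm38 and GENCODE M21), was lower in the epithelial-like cells of both Trp53-deleted libraries. It stood at 59.9 CPM (57.0 to 62.8) in Trp53-intact mice, 93.3 CPM (88.4 to 98.4) in Trp53-intact ADT, 18.8 CPM (16.7 to 21.1) in Trp53-deleted mice and 18.8 CPM (15.2 to 23.02) in Trp53-deleted ADT. In fibroblast-like cells Trp53 was 44.9, 69.5, 46.3 and 44.1 CPM, which without ADT differed little between the genotypes, while with ADT the value was lower in the Trp53-deleted library here too (39.3 to 49.3 against 64.95 to 74.3). Which exons were deleted is not given in the sources used here, and a 3' tag outside the deleted part counts RNA that still carries the gene's end, so these values do not check the deletion.

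The CDK inhibitors Cdkn1a (chromosome 17, 29090976 to 29100727), a direct p53 target, and Cdkn2a (chromosome 4, 89274471 to 89294653), the locus of p16 and p19ARF, went opposite ways between the genotypes. In luminal progenitor-like cells Cdkn1a was 190, 363, 56.2 and 174 CPM, and Cdkn2a 81.2, 147, 463 and 440 CPM. Neutrophil-like cells held 4.04, 6.16, 14.1 and 154 CPM of Cdkn2a, so free RNA carried the gene in the Trp53-deleted ADT library.

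**Figure D2:**
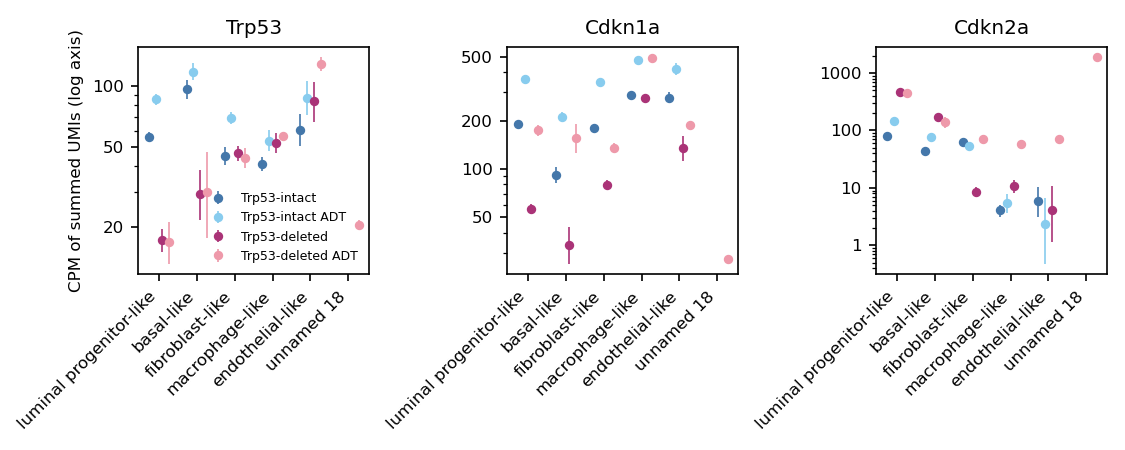
CPM of summed UMIs (log axis) of Trp53, Cdkn1a and Cdkn2a in 5 cell classes and in unnamed cluster 18, per library (colours), with exact 95% Poisson intervals. Trp53 in luminal progenitor-like cells stands at 56.0 and 85.5 CPM in the Trp53-intact libraries and at 17.3 and 16.9 CPM in the Trp53-deleted libraries.

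The comparison of ADT with no ADT in Trp53-intact mice asks how androgen deprivation alters prostate cells. Several secretory genes of the prostate were among those with the lowest ratios. In luminal progenitor-like cells the prostate defensin Defb50 (chromosome 8, 21823539 to 21831296) stood at 4016 CPM without ADT and at no UMI with it, and probasin, Pbsn (chromosome X, 77837901 to 77853623), an androgen-driven secretory protein, at 317 against 0.185 CPM. Microseminoprotein Msmb (300 CPM) and the prostate transglutaminase Tgm4 (91.7 CPM) had no UMI with ADT. Pbsn, Msmb, Defb50 and Tgm4 lead cluster 9, and Defb50 also stood at 298 CPM in the neutrophil-like cells of the Trp53-intact library, where it is background.

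Of 36 measured androgen-response genes, 19 were at least 1.5-fold lower with ADT in Trp53-intact epithelial-like cells and 3 higher, and the median log2 ratio was -0.62 (percentile 0 of random lists). Ndrg1 (83.9 against 43.8 CPM) and Abcc4 (55.2 against 28.5 CPM) were the highest members. The median was -1.02 with a pseudocount of 1 CPM, -2.07 over members highest in epithelial-like cells, and -0.50 in luminal progenitor-like cells alone. Within these cells it was -0.38 after the neutrophil-like CPM of each library was taken off. Other genes lower with ADT were the matrix protease Mmp7 (669 against 4170 CPM), the antimicrobial lectin Reg3b (17.7 against 251 CPM), the ribonuclease Rnase1 (1.53 against 382 CPM), the defensin Defb1 (20.4 against 524 CPM), and Wfdc18, Spink5, Apof and Sbp. Mmp7 and Wfdc18 stood at 253 and 198 CPM in neutrophil-like cells of the Trp53-intact library. Genes higher with ADT were the carbonic anhydrase Car12 (172 against 24.1 CPM), the neutrophil chemokine Cxcl5 (808 against 239 CPM), the secreted glycoprotein Olfm4 (172 against 44.3 CPM), the GABA receptor subunit Gabrp (334 against 92.9 CPM), the pantetheinase Vnn1 (31.8 against 2.85 CPM), the homeobox gene Meis2 (452 against 132 CPM), Ltbp2 (107 against 20.7 CPM), Dapl1, BC100530, Fam71a, Adgra1 and Lgals7. The luminal progenitor-like class joins cluster 8, with 437, 218, 280 and 105 cells, and the shallower cluster 19, with 192, 236, 68 and 92. Mmp7, Wfdc18, Tff3 and Fcgbp are among the genes that lead cluster 8 and Car12 among those of cluster 19, so ratios in this class also carry the mix of the clusters.

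Several lists tied to immune responses had higher medians with ADT in Trp53-intact mice. The neutrophil gene S100a8 was 21.4 against 10.1 CPM in these epithelial-like cells and 61.2 against 9.95 CPM in fibroblast-like cells, so RNA of immune cells is not excluded. Of the neutrophil-attracting and myeloid-attracting ligands, 12 were higher and 1 lower (median 0.65), with Ppbp at 12.2 CPM against no UMI and Ccl20 at 227 against 76.7 CPM. The senescence and secretory factors had 7 higher and 3 lower (median 0.31). Interferon response genes had 21 higher and 1 lower (median 0.76), such as Iigp1 (35.7 against 9.59 CPM) and Ifit3 (191 against 65.2 CPM), and MHC class I genes 6 higher and 1 lower (median 0.51). Both lists were also higher against this same Trp53-intact library in Trp53-deleted mice without ADT, so a trait of that library is not excluded. Basal keratins and stem genes had 7 higher and 0 lower (median 0.52), led by Krt14 (502 against 196 CPM), along with a basal-like share of epithelial-like cells of 19.9% against 8.47%. The median was 0.23 in luminal progenitor-like cells, where Krt14 was 46.3 against 34.0 CPM. Cholesterol and lipid synthesis had 0 higher and 9 lower of 25 (median -0.34), with the sterol sensor Insig1 at 7.99 against 33.1 CPM. The unfolded protein response had 1 higher and 9 lower (median -0.56), with Sdf2l1 at 29.1 against 79.8 CPM, and cell cycle genes had 0 higher and 8 lower (median -0.27), with Ube2c at 3.54 against 15.9 CPM. Dissociation stress genes, which respond to tissue handling, had 12 higher and 2 lower (median 0.86). Fosb was 1623 against 427 CPM, while the heat shock gene Hspa1a was 63.7 against 639 CPM.

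ADT against no ADT in Trp53-deleted mice asks the same where Trp53 is lost too. Some secretory genes were again among those with the lowest ratios, while the genes with the highest ratios were partly others. In luminal progenitor-like cells spermine-binding protein Sbp was 532 CPM without ADT and had no UMI with it, Defb50 was 686 CPM against no UMI, the mucosal trefoil peptide Tff3 555 against 1.85 CPM, and the membrane protease Mme 96.4 against 3.004 CPM. Pbsn (11.8 CPM) had no UMI in epithelial-like cells with ADT, which allows up to 0.606 CPM. Of 35 androgen-response genes, 21 were lower and 2 higher (median -0.94, percentile 0), with Ndrg1 at 132 against 33.6 CPM. The median was -1.55 over members highest in epithelial-like cells. Also lower with ADT were Spink5 (2.02 against 175 CPM), Fcgbp (19.8 against 242 CPM), the acute-phase gene Saa1 (9.70 against 100.4 CPM), Wfdc18, Sval1 and BB123696. Igha and Jchain, immunoglobulin genes that lead the plasma-like cluster, were lower too (9.29 against 481 CPM and 3.03 against 230 CPM; 123 and 162 CPM in neutrophil-like cells without ADT).

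Higher with ADT in Trp53-deleted luminal progenitor-like cells were Ly6d (6145 against 1389 CPM) and Ly6k (686 against 219 CPM), both GPI-anchored surface proteins, Dmkn (84.3 against 5.40 CPM) and Sbsn (177 against 35.8 CPM), genes of cornifying epithelium, Car12 (156 against 20.8 CPM), Prss22 (98.6 against 17.9 CPM), Vnn1 (41.8 against 4.80 CPM), AC122397.2 and the uroplakin Upk3a (73.5 against 15.3 CPM). Gstm1 (661 against 57.6 CPM), Aqp3 (51.3 against 5.66 CPM) and Fmo5 (43.4 against 4.10 CPM) were higher only over all epithelial-like cells. In luminal progenitor-like cells they were 54.1 against 50.9, 1.39 against 1.80 and 4.16 against 3.53 CPM.

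MHC class II genes had 6 of 8 members higher with ADT in Trp53-deleted mice and 0 lower (median 1.41), led by the invariant chain Cd74 (893 against 143 CPM). The median was 1.56 in luminal progenitor-like cells. The immune genes S100a8 (27.5 against 6.18 CPM) and Ptprc (9.70 against 5.34 CPM) were higher in epithelial-like cells too, and Cd74 was 661 against 374 CPM in neutrophil-like cells, so RNA of immune cells is not excluded. Senescence and secretory factors had 10 higher and 1 lower (median 0.51), and neutrophil-attracting and myeloid-attracting ligands 12 higher and 3 lower (median 0.67), with Cxcl3 at 68.3 against 12.7 CPM. Glycolysis and hypoxia genes had 7 higher and 0 lower (median 0.11), with the hypoxia-induced Car9 at 45.3 against 7.94 CPM. Cell cycle genes had 7 higher and 0 lower (median 0.15), and neuroendocrine and plasticity genes 5 higher and 0 lower (median -0.02, mean above 0), with the granin Chga at 24.4 CPM against no UMI. Cholesterol and lipid synthesis had 0 higher and 8 lower (median -0.38), such as Fasn (26.3 against 55.4 CPM), and basal keratins and stem genes 1 higher and 6 lower (median -0.29). Interferon response genes had 3 higher and 1 lower (median -0.002, mean above 0). Epithelial to mesenchymal genes had 14 higher and 1 lower (median 0.76), with Lgals1 at 176 against 10.3 CPM and Col1a1 at 86.7 against 4.69 CPM. Collagens and Lgals1 also mark cluster 18 of this library, whose RNA was found in other classes. Dissociation stress genes had 16 higher and 0 lower (median 0.69).

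The ADT ratios of the 2 genotypes, which share no library, were related across genes in epithelial-like cells. Pearson's r was 0.536 and Spearman's rho 0.423 over 7062 genes, and r was 0.579 and rho 0.483 over 7002 genes in luminal progenitor-like cells. Genes of 1 sample are not independent replicates. Of 395 genes at least 2-fold apart with ADT in Trp53-intact mice, 86.1% lay in the same direction in Trp53-deleted mice. In other classes r was lower, at 0.378 in macrophage-like, 0.146 in fibroblast-like, 0.015 in neutrophil-like, -0.085 in T-like and -0.054 in endothelial-like cells. The steroid receptors Esr1 (79.9 against 24.4 CPM in Trp53-intact mice, 57.8 against 18.4 CPM in Trp53-deleted mice) and Pgr (8.34 against 0.0740 and 6.06 against 0.0651 CPM), and Srd5a1 (40.5 against 10.9 and 58.2 against 17.2 CPM), which makes dihydrotestosterone, were higher with ADT in both genotypes. The steroid and androgen metabolism list had 3 higher and 2 lower in Trp53-intact mice (median 0.10) and 3 higher and 1 lower in Trp53-deleted mice (median -0.03, mean above 0).

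Targets of p53 had 4 higher and 1 lower with ADT in Trp53-intact mice (median 0.13) and 5 higher and 2 lower in Trp53-deleted mice (median 0.03), with Cdkn1a higher in both, at 325 against 176 CPM and 171 against 52.9 CPM. JAK-STAT and interleukin 6 family genes had 5 higher and 1 lower in Trp53-intact mice (median 0.27) and 8 higher and 1 lower in Trp53-deleted mice (median 0.08), and the feedback inhibitor Socs3 was 69.9 against 19.99 CPM and 59.0 against 26.1 CPM. Socs3 and Junb are also on the dissociation stress list, which was higher with ADT in both genotypes, so tissue handling is not excluded for them. PI3K-AKT-mTOR output had 1 higher and 1 lower in Trp53-intact mice (median 0.10), with the D-type cyclin Ccnd2 at 182 against 67.4 CPM, and 0 higher and 1 lower in Trp53-deleted mice (median -0.095). Luminal progenitor genes had 6 higher and 2 lower in Trp53-intact mice (median -0.09) and 4 higher and 1 lower in Trp53-deleted mice (median -0.05, mean above 0), while the retinal dehydrogenase Aldh1a1 was lower in both (12.3 against 94.3 CPM and 8.08 against 54.2 CPM). Percentiles among random lists were 87.87 and 97.71 for p53 targets, 99.71 and 98.555 for JAK-STAT, 65.84 and 52 for PI3K-AKT-mTOR and 23.89 and 20.66 for luminal progenitor genes.

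**Figure D3:**
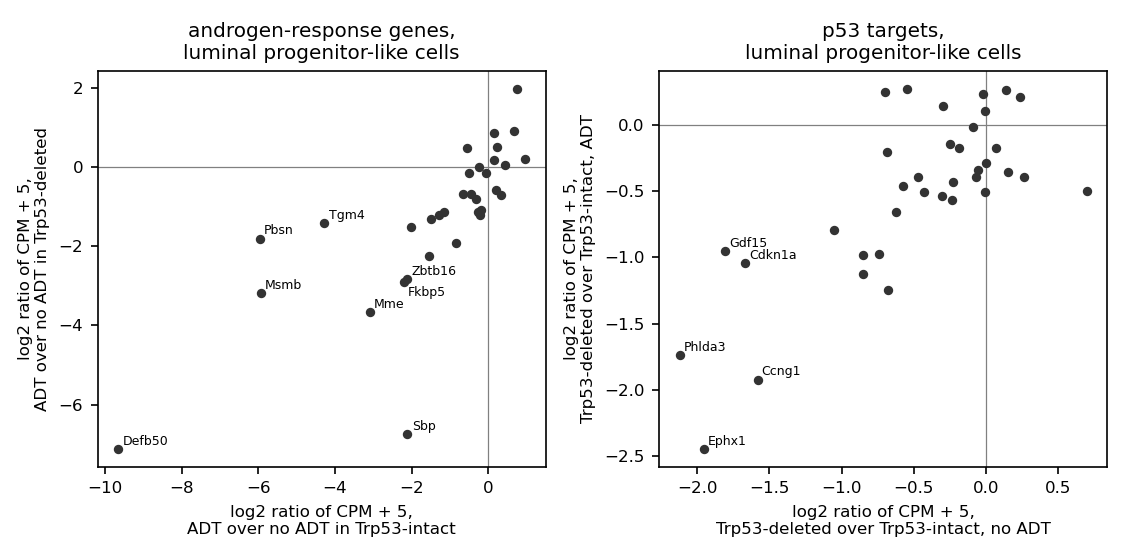
Log2 ratios of CPM plus 5 in luminal progenitor-like cells, 1 point per list member shown. Left, androgen-response genes with ADT in Trp53-intact mice (horizontal) and in Trp53-deleted mice (vertical); right, p53 targets in Trp53-deleted mice over Trp53-intact mice without ADT (horizontal) and with ADT (vertical). Most points lie below 0 on both axes in each panel.

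Trp53-deleted mice against Trp53-intact mice without ADT asks what loss of Trp53 adds. Targets of p53 were lower in the Trp53-deleted library. Of 37 measured, 12 were at least 1.5-fold lower and 1 higher in epithelial-like cells, with a median log2 ratio of -0.32 (percentile 0). Gdf15, a stress-induced secreted factor, was 5.60 against 29.1 CPM, Cdkn1a 52.9 against 176 CPM, the epoxide hydrolase Ephx1 18.2 against 62.3 CPM, and Ccng1 42.3 against 126 CPM. The 1 higher member was Tap1 (78.9 against 43.3 CPM), which is also an interferon-induced gene. The median was -0.48 with a pseudocount of 1 CPM and -0.15 over members highest in epithelial-like cells. Cdkn2a was 426 against 79.5 CPM.

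Also higher in Trp53-deleted mice were the mucosal and secretory genes Psca (639 against 246 CPM), Sftpd (73.1 against 17.7 CPM), Scgb3a1 (22.1 against 2.52 CPM), Gkn3 (24.3 against 0.296 CPM), Msln (132 against 41.4 CPM), Saa1 (100.4 against 10.1 CPM) and Olfm4 (128 against 44.3 CPM), with Sbp, Igha, BB123696 and Spink5. Lower were the androgen-driven genes Pbsn (11.8 against 406 CPM), Msmb (36.1 against 489 CPM), Tgm4 (7.81 against 144 CPM), Defb50 (614 against 5196 CPM) and Rnase1 (45.04 against 382 CPM), and Defb1, Mmp7, Prr9, Reg3b, Krt17 (56.2 against 221 CPM), Snhg9 and AL732506.1. Pbsn, Msmb, Tgm4, Defb50, Rnase1 and Defb1 lead cluster 9, which held 14.8% against 53.5% of epithelial-like cells. In luminal progenitor-like cells Pbsn was 12.5 against 317 CPM, Msmb 40.5 against 299.8 CPM, Tgm4 8.41 against 91.7 CPM and Defb50 686 against 4016 CPM. Pbsn, Defb50, Defb1, Mmp7 and Snhg9 were lower in every class measured, with Defb50 at 28.3 against 298 CPM in neutrophil-like cells, so the values hold free RNA. As a list, androgen-response genes had 9 higher and 6 lower members (median 0.17, mean below 0). Interferon response genes had 18 higher and 0 lower (median 0.61), such as Gbp3 (27.7 against 7.37 CPM) and Ifit3 (155 against 65.2 CPM), and MHC class I genes 8 higher and 0 lower (median 0.59). Cholesterol and lipid synthesis had 5 higher and 0 lower (median 0.35), whereas the unfolded protein response had 0 higher and 8 lower (median -0.46), such as Creld2 (29.8 against 59.9 CPM). The comparison of ADT with no ADT in Trp53-intact mice has the same Trp53-intact library as its reference. There the interferon, MHC class I and unfolded protein response medians went the same ways. Comparisons without that library had no higher interferon median, so a trait of that library cannot be told apart from genotype or ADT. MHC class II had 0 higher and 4 lower (median -0.25), and basal keratins and stem genes 1 higher and 1 lower (median 0.29). Dissociation stress genes had 0 higher and 5 lower (median -0.35), with Hspb1 at 621 against 2040 CPM.

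With ADT, p53 targets were again lower in the Trp53-deleted library, with 12 of 37 lower and 0 higher (median -0.405, percentile 0). Ephx1 was 18.6 against 93.3 CPM, Ccng1 23.8 against 86.9 CPM and Phlda3, an AKT inhibitor, 37.6 against 103 CPM. Trp53 was itself among the 12 lowest genes. Of 17 basal keratins and stem genes, 7 were at least 1.5-fold lower and 0 higher (median -0.50). Lower members were Krt5 (145 against 513 CPM), Krt14 (174 against 502 CPM) and the hemidesmosome collagen Col17a1 (22.8 against 87.9 CPM). These 3 genes lead the basal-like cluster, which held 14.83% of epithelial-like cells against 19.9%. The vasoconstrictor Edn1 (197 against 771 CPM), the chemokine Ccl20 (63.2 against 227 CPM), Ifi202b (35.4 against 96.5 CPM), the DNA repair gene Mgmt (2.42 against 19.7 CPM), Pik3c3, Amd2, Slco1a5 and AL732506.1 were lower too. Cell cycle genes had 17 higher and 1 lower (median 0.40), such as Ube2c (39.8 against 3.54 CPM) and Birc5 (19.4 against 3.82 CPM), in a library where RNA of cluster 18 made up an estimated 1.56% of that in luminal progenitor-like cells, and neuroendocrine and plasticity genes 5 higher and 1 lower (median 0.40), with Onecut2 at 23.2 against 0.348 CPM.

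Psca (559 against 148 CPM), Hspa1b (444 against 112 CPM), the cornified envelope gene Sprr1a (556 against 214 CPM), Upk3a (262 against 33.5 CPM), Acaa1b, AC122397.2, Ly6g6c and Clca3b were higher in Trp53-deleted mice with ADT. Gstm1, Aqp3, Fmo5 and Upk2 were higher over all epithelial-like cells (661 against 60.5, 51.3 against 5.28, 43.4 against 3.68 and 24.8 against 2.78 CPM), though not in luminal progenitor-like cells, where Upk2 was 3.47 against 3.52 CPM. MHC class II genes had 5 higher and 0 lower (median 0.71), epithelial to mesenchymal genes 12 higher and 3 lower (median 0.66), and cholesterol and lipid synthesis 3 higher and 0 lower (median 0.33). Interferon response genes had 2 higher and 4 lower (median -0.18). Androgen-response genes had 3 higher and 1 lower of 24 (median 0.12). The Trp53 ratios without and with ADT were nearly unrelated across genes (r 0.088, rho 0.067).

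Cluster 18 stood apart in the Trp53-deleted ADT library. It held 641 cells there (7.25%), 1 in Trp53-deleted mice and none in the other libraries (at most 0.0492% and 0.0507%). These cells were deep, with a median of 82090.0 UMIs in that library, and were led by genes of matrix-producing cells such as Postn, Cthrc1, Col1a1, Ptn and Tnc, together with Cdkn2a, Crabp1 and Stmn2. They carried Vim at 4174 CPM and the epithelial genes Epcam, Krt8 and Krt18 at 2.37, 3.39 and 7.11 CPM. Their Trp53 was 20.4 CPM (19.3 to 21.6), against 44.1 CPM in fibroblast-like, 56.4 CPM in macrophage-like and 127 CPM in endothelial-like cells of the library. Neutrophil-like cells had a like level of 16.04 CPM (9.80 to 24.8). Their Cdkn2a was 1864 CPM, a ratio of 25.9 (23.7 to 28.3) over fibroblast-like cells, and Cdkn1a was 27.5 CPM. Median expression per chromosome, relative to fibroblast-like cells, was 0.56 on chromosome 3 and 0.42 on chromosome 5, and -0.87 on chromosome 8, -0.78 on chromosome 14 and -0.55 on chromosome 10. Chromosome 14 lay below the 5th percentile of fibroblast-like cells in 96.4% of the 641 cells, against 12.6% of endothelial-like cells. Endothelial-like cells left the fibroblast-like range more often on other chromosomes, with 53.4% above it on chromosome 5 and 40.9% below it on chromosome 10, against 89.9% and 86.3% of cluster 18 cells. Cluster 4, shallow cells of the same library (17.2% of its cells, median 1111 UMIs), had Cdkn2a, Crabp1 and Postn among its leading genes, with chromosome medians of 0.46 on chromosome 3 and -0.64 on chromosome 8.

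**Figure D4:**
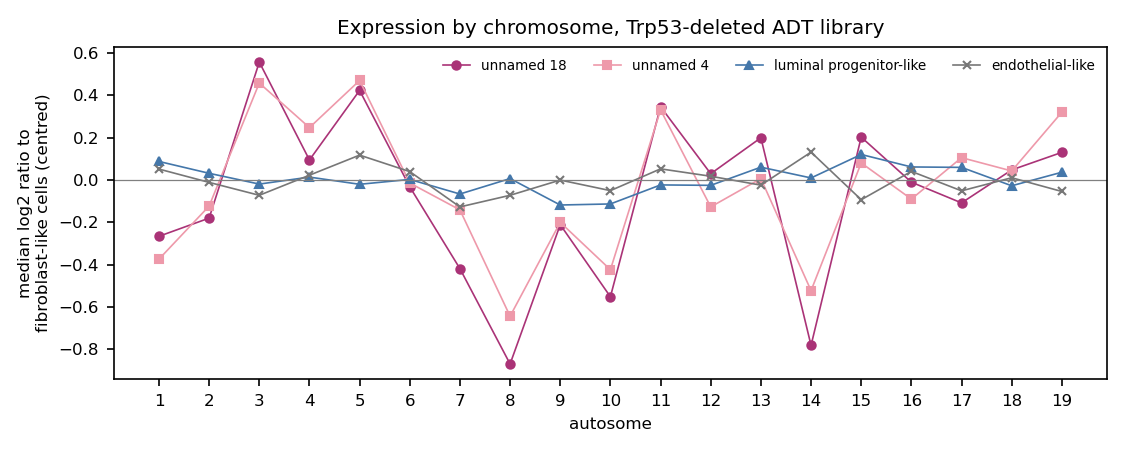
Median log2 ratio to fibroblast-like cells, centred on all autosomal genes (vertical axis), per autosome (horizontal axis) in the Trp53-deleted ADT library, for unnamed clusters 18 and 4, luminal progenitor-like and endothelial-like cells. The clusters 18 and 4 share their low points at chromosomes 8 (-0.87 and -0.64) and 14 (-0.78 and -0.52); the endothelial-like line reaches 0.13 at most.

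Fibroblast-like cells came from clusters 1, 6, 16 and 22, which differed by library. Cluster 1, led by the oestrogen sulfotransferase Sult1e1, Col6a5 and C7, held 929, 38, 1244 and 35 cells, and cluster 6, led by Apod, Mmp3 and Igfbp3, held 12, 851, 25 and 233. Cluster 16, led by Lgr5 and Wif1, held 37, 178, 214 and 245 cells, and cluster 22, led by Mfap4, Cxcl14 and Mgp, held 126, 101, 20 and 269. Among genes leading no cluster, the natriuretic peptide Nppc was 41.5 against 2.04 CPM and Fosb 3160 against 719.5 CPM with ADT in Trp53-intact mice, and Rbp4 was 213 against 18.5 CPM with ADT in Trp53-deleted mice. Of 25 fibroblast activation genes, 2 were higher and 10 lower with ADT in Trp53-intact mice (median -0.31), with Col3a1 at 1280 against 5578 CPM. In Trp53-deleted mice, 14 were higher and 3 lower (median 0.71), with smooth muscle actin Acta2 at 162 against 9.62 CPM and Tnc at 42.6 against 2.06 CPM. Cluster 18 carries both (573.5 and 285.6 CPM) and Tnc stood at 50.5 CPM in neutrophil-like cells with ADT, so free RNA is not excluded for this list. Against Trp53-intact mice, the list had 2 higher and 10 lower without ADT (median -0.33) and 15 higher and 2 lower with ADT (median 0.87), where free RNA of cluster 18 also carries collagens. With ADT in Trp53-deleted mice, cluster 22 made up 34.4% of fibroblast-like cells against 1.33%, and cluster 16 31.3% against 14.2%, so the list also carries the mix of clusters. Metallothionein Mt2, which leads cluster 6, was 384 CPM in Trp53-deleted ADT against 4471 CPM in Trp53-intact ADT, and it was lower in all 8 classes measured (6.42 against 97.2 CPM in neutrophil-like cells).

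Macrophage-like cells came from clusters 2, 5, 20 and 21. Cluster 5, led by genes of resident macrophages (Cd209f, Folr2, Cd163), held 904, 64, 468 and 67 cells, and cluster 2, led by Ms4a4c and Cx3cr1, held 24, 55, 42 and 2073. Cluster 2 had as many monocyte as macrophage markers among its leading genes, so the values below also carry the mix of these clusters. Macrophage alternative activation genes were lower with ADT in Trp53-deleted mice, with 0 higher and 16 lower of 21 (median -1.69). Retnla was 88.1 against 2237 CPM, Clec10a 31.7 against 706 CPM and Gpnmb 18.8 against 388 CPM, and Clec10a is among the genes that lead cluster 5 and Gpnmb among those of cluster 21. Retnla leads monocyte-like cluster 24 and was lower in all 8 classes measured (10.4 against 121 CPM in neutrophil-like cells). In Trp53-intact mice the list had 6 higher and 9 lower (median -0.27), with arginase Arg1 at 134 against 16.7 CPM and Spp1 at 1579 against 435 CPM, and Folr2 at 55.4 against 292 CPM. The phagocytic bridge Mfge8 was 680 CPM with ADT against 52.1 CPM. Against Trp53-intact mice, Trp53-deleted mice had 6 higher and 1 lower without ADT (median 0.40) and 1 higher and 14 lower with ADT (median -1.67). Macrophage inflammatory genes had 7 higher and 3 lower with ADT in Trp53-deleted mice (median 0.19), with Il1b at 1843 against 486 CPM, and 5 higher and 5 lower in Trp53-intact mice (median 0.05). In Trp53-deleted mice against Trp53-intact mice they had 0 higher and 8 lower without ADT (median -0.56), with Ccl4 at 742 against 2316 CPM, and 1 higher and 5 lower with ADT (median -0.14). Thbs1 (504 against 23.9 CPM), Nr4a2 (362 against 42.4 CPM) and the glucocorticoid-induced Fkbp5 (112 against 26.8 CPM) and Tsc22d3 (229 against 68.6 CPM) were higher with ADT in Trp53-deleted mice.

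Neutrophil suppressive genes in neutrophil-like cells had 0 higher and 6 lower with ADT in Trp53-intact mice (median -0.38). In Trp53-deleted mice, 2 were higher and 10 lower of 16 (median -0.65), and the checkpoint ligand Cd274 was 301 against 877 CPM. Cd274 leads cluster 10, which held 174, 298, 289 and 105 neutrophil-like cells beside 576, 905, 490 and 372 in cluster 0. Against Trp53-intact mice, Trp53-deleted mice had 3 higher and 3 lower without ADT (median 0.16) and 2 higher and 4 lower with ADT (median -0.37). T-like cells with ADT in Trp53-intact mice had lower regulatory T genes, with 0 higher and 8 lower of 9 (median -1.05), such as Ikzf2 (197 against 767 CPM), and lower T-cell inhibitory receptors, with 1 higher and 5 lower (median -0.59), such as Pdcd1 (45.5 against 196 CPM). These values go with another mix of clusters, since cluster 17, led by Ikzf2, Ctla4 and Foxp3, held 149, 109, 230 and 169 T-like cells and cluster 13, led by Lef1 and Tcf7, held 17, 403, 188 and 188. Their Cd8a was 134 against 5.65 CPM and Il17a 27.2 against 349.5 CPM, genes that lead the clusters of this class or of NK-like cells. Cluster 14, led by Il17a, held 213, 203, 69 and 285 of the 382, 723, 489 and 655 T-like cells, so Il17a also goes with the mix of clusters. With ADT in Trp53-deleted mice, regulatory T genes had 1 higher and 4 lower (median -0.10), T-cell inhibitory receptors 2 higher and 1 lower (median 0.31), and Il17a was 192 against 18.3 CPM. The cytotoxic list in T-like cells had 4 higher and 4 lower with ADT in Trp53-intact mice (median 0.09) and 4 higher and 0 lower in Trp53-deleted mice (median 0.27).

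The share of cycling epithelial-like cells after thinning was 1.98%, 1.17%, 1.62% and 3.28%, with 742, 64, 86 and 53 shallower cells left out. Without thinning it was 5.08%, 5.88%, 8.29% and 17.4% at median depths of 2564, 11718.5, 20841 and 11349.5 UMIs. In neutrophil-like cells the thinned share was 0% in both Trp53-intact libraries (at most 0.418% and 0.258%), 0.368% in Trp53-deleted mice and 4.81% in Trp53-deleted ADT, at depths of 3234.5, 3562, 2631 and 2607 UMIs. The epithelial-like share of that library does not exceed this, though RNA of cluster 18 was estimated at 10.67% in neutrophil-like and 1.56% in luminal progenitor-like cells, so the background of the epithelial-like share is not settled. Endothelial-like cells stood above the neutrophil-like share there, with 14.0% thinned (10.4 to 18.4) against 1.81%, 0% (at most 2.52%) and 0% (at most 2.94%) elsewhere. Endothelial-like cell cycle genes had 37 of 40 members higher with ADT in Trp53-deleted mice (median 2.07), with Top2a at 123 against 3.14 CPM, while Fabp4 (486 against 5882 CPM) and the fatty acid receptor Cd36 (52.3 against 794 CPM) were lower. Macrophage-like cells were cycling in 6.81%, 16.5%, 5.47% and 11.1%, while cluster 20, led by Top2a and Mki67, made up 8.19%, 30.1%, 6.88% and 12.2% of them. Cluster 18 cells were cycling in 28.4%.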

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

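Of the tests below, the copy number test and the tests of free RNA and of UMIs per cell for androgen-response genes were written before their results were seen, and the others after. The ratios and list medians of the next paragraph were singled out because ADT went with opposite directions in the 2 genotypes, and the other results for other reasons. The differences between genotypes were not tested, as each group has 1 library.

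The ratio of the macrophage-like share with ADT to that without was 0.2581 in Trp53-intact mice and 2.397 in Trp53-deleted mice, that of the dendritic-like share 0.4543 and 1.761, and that of macrophage, monocyte and dendritic-like cells together 0.3036 and 1.82. In Trp53-deleted mice the direction of these 3 was lost in other settings, with differences of -6.89, -1.09 and -7.98 points with doublets kept and -9.14, -1.26 and -10.4 with the mitochondrial limit of 50%, and of -1.06 for dendritic-like cells at resolution 0.5. Neutrophil-like cells went the other way, with 1.655 in Trp53-intact mice and 0.3729 in Trp53-deleted mice, as did B-like cells, with 3.383 and 0.2574. The smaller classes had ratios of 0.3821 and 2.964 for erythroid-like and 0.258 and 2.537 for mesothelial-like cells, the 0.258 from 2 against 8 cells (interval 0.02668 to 1.292). The epithelial to mesenchymal list had medians of -0.898 in Trp53-intact mice and 1.359 in Trp53-deleted mice in T-like cells and of -0.652 and 1.396 in NK-like cells, and the fibroblast activation list had -1.745 and 1.683 in NK-like cells. These lists hold matrix genes that lymphocytes should lack, and Postn stood at 226 CPM in neutrophil-like cells of the Trp53-deleted ADT library.

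The cells of cluster 18 were found almost entirely in the Trp53-deleted ADT library. Mixtures of epithelial-like with other cells were argued against by 40 luminal markers, whose median CPM was 0.00122 of that in epithelial-like cells. For fibroblast-like cells of the same library with more UMIs, the Trp53 ratio was 0.463 (0.408 to 0.527). Trp53 differed widely between the classes of this library, with a ratio of 0.161 to endothelial-like cells. The ratio to fibroblast-like cells therefore cannot decide whether cluster 18 is a state of such cells. Lack of intact Trp53 was consistent with a ratio of 1.21 (0.956 to 1.56) to luminal progenitor-like cells, although the ratio to neutrophil-like cells was 1.27 (0.821 to 2.09), so a low level alone does not show a deletion. The cells were also consistent with shared copy number changes, given the median of -0.87 on chromosome 8, where endothelial-like cells reached 0.132 at most on any autosome. The origin of these cells was not tested and stays open, as does a trait of 1 mouse alone.

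Cell cycle genes were higher in several classes of the Trp53-deleted ADT library. Free RNA from cluster 18, at an estimated 10.67% of the RNA in neutrophil-like cells, gave a median ratio of observed to predicted cell cycle genes there of 1.48 (0.685 to 3.54 over 10 genes), so it may account for part of their level. It fell short in T-like (5.4), macrophage-like (15.7), luminal progenitor-like (11.3) and endothelial-like cells (19.8), which argues against free RNA from this cluster as the whole source in these classes. It stays open in B-like (1.45) and NK-like cells (2.29), and free RNA of other cycling cells stays open in all classes.

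Androgen-response genes were lower with ADT in both genotypes. Fewer luminal-like cells in the sum, as the whole source, were argued against by medians within luminal progenitor-like cells. These were -0.503 in Trp53-intact mice and -1.098 in Trp53-deleted mice. Less free RNA from the missing luminal-like cells would lower these medians too and is taken up below. The mix of clusters 8 and 19 in this class also differed with ADT and was not held fixed. Different UMIs per cell were argued against by thinned medians of -0.812 and -0.892. Less free RNA of secretory cells was argued against in Trp53-deleted mice by a median of -1.194 after neutrophil-like CPM was taken off. In Trp53-intact mice the value was -0.382, short of the -0.4 set beforehand, so less free RNA and lower expression cannot be told apart for that library. Age, which differs with ADT, is an open and untested difference.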

How the results depend on the processing

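The mitochondrial limit of 50%, the counting of cluster 3, luminal progenitor-like cells only and every alternative for immune classes were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Of 88 alternatives for epithelial-like shares and list medians, 47 stayed within the counting interval, 40 moved and 1 reversed. The epithelial-like difference with ADT in Trp53-intact mice (-14.08 points) was -6.19 with the stricter filter, -3.24 with doublets kept, -1.49 and -5.18 at Leiden resolutions 0.5 and 2.0, 1.76 with each library clustered on its own, -7.74 with the mitochondrial limit of 50% and -1.45 with cluster 3 counted. In Trp53-deleted mice (-6.97) these were -4.86, -5.06, -5.23, -4.99, -0.58, -6.11 and -5.21. For Trp53-deleted mice against Trp53-intact mice without ADT (-12.39) it was -8.25 with the stricter filter, -15.96 at resolution 0.5, -6.37 with each library on its own, -14.13 with the other denominator and -15.92 with cluster 3 counted. With ADT (-5.28) it was -6.92, -13.25, -19.7, -12.48, -8.71 and -10.99 in the order given for Trp53-intact mice, then -6.64 with the other denominator and -19.68 with cluster 3. At resolution 0.5 the values lie close to those with cluster 3 counted, and 99.83% of its 1785 cells were named epithelial-like there. In the other settings the cause was not tested. The most common name in cluster 3 was epithelial-like with doublets kept (52.77%), at resolution 2.0 (54.51%) and with each library on its own (42.75%), but macrophage-like with the mitochondrial limit of 50% (53.33%).

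The androgen-response gene median with ADT in Trp53-intact mice (-0.62) was -0.72 with the stricter filter, -0.5 in luminal progenitor-like cells, -0.73 as a mean over cells, -1.02 with a pseudocount of 1 CPM and -2.07 over members highest in epithelial-like cells. In Trp53-deleted mice (-0.94) it was -0.78 with the stricter filter, -0.81 as a mean over cells and -1.55 over those members. The p53 target median without ADT (-0.32) was -0.41 with TMM factors, -0.48 with a pseudocount of 1 CPM and -0.15 over members highest in epithelial-like cells, and with ADT (-0.4) -0.34 thinned, -0.5 as a mean over cells and -0.51 with a pseudocount of 1 CPM. These 4 medians kept their direction in all 14 alternatives each; the pseudocount acts through low counts, and the cause of the other moves was not tested. Of 60 alternatives for immune shares, 7 reversed, all with ADT in Trp53-deleted mice. The macrophage-like difference (16.22) was -6.89 with doublets kept and -9.14 with the mitochondrial limit of 50%, and that of macrophage, monocyte and dendritic-like cells (14.29) was -7.98 and -10.4. In both settings over 97% of the cells of cluster 2 lost their name, as 5 markers of another class stood among the leading 10 against 2 of its own. The dendritic-like difference (1.57) was -1.09, -1.26 and, at resolution 0.5, -1.06, and the cause was not tested. Depth limits the shallow clusters, such as 3 and 4, and the 236 epithelial-like cells of the Trp53-deleted ADT library.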

Other observations

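Small unnamed clusters pointed to cell types outside the marker lists. Cluster 39, led by the osteoclast genes Ctsk, Acp5 and Ocstamp, held 58 cells, all in the Trp53-deleted ADT library. Cluster 35, led by intestinal genes such as Muc2, Lgals4 and Guca2a, held 54, 1, 0 and 62 cells. Cluster 43, led by neuronal genes such as Tubb3, Snap25 and Npy, held 13, 5, 4 and 0 cells, and cluster 36, led by Ccr3 and Alox15, genes of eosinophils, held 49, 37, 1 and 3. With 1 library per group, such cells may be a matter of dissection or of 1 mouse, as may cluster 18 with its median of -0.87 on chromosome 8.

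Some genes were at least 2-fold apart in the same direction in every class measured, the mark of a difference between whole libraries. With ADT in Trp53-intact mice, 4 genes were higher and 13 lower in this way, with ADT in Trp53-deleted mice 10 and 19, in Trp53-deleted mice against Trp53-intact mice 9 and 20 without ADT and 14 and 8 with ADT. The heat shock gene Hspa1a was 2.01 CPM in T-like cells of the Trp53-intact ADT library and 1299 CPM in those of the Trp53-intact library. The seminal vesicle gene Svs4 was 603.5 CPM in neutrophil-like cells of the Trp53-deleted library and 0.802 CPM with ADT. Gdpd3 was 205 CPM in neutrophil-like cells of the Trp53-intact ADT library and 14.55 CPM in those of the Trp53-intact library, and the collagen chaperone Serpinh1 was 188.5 CPM in those of Trp53-deleted ADT and 19.7 CPM without ADT. These examples were chosen after their values were seen.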
